A study of Mus musculus with 12 samples.

How the data were processed

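RNA-seq of 12 libraries from mouse spermatogonial stem cells was analysed, 2 biological replicates in each of 6 groups. RNA was extracted with TRIZOL, treated with DNase I and sequenced on an Illumina HiSeq instrument. The deposited values are FPKM, which the authors computed, per the submitters' processing notes, with TopHat2 2.0.6 and Cuffdiff on the mm9 assembly. The version and scaling options of Cuffdiff are not given in the sources used here. Reads were not used here, so the absolute depth of each library is unknown. The spacing of the lowest FPKM values gave relative depths between 83.5% and 99.3% of the first library of each experiment.

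Values were analysed in R 4.3.3 with limma 3.58.1 and jsonlite 2.0.0, and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Copies of one symbol were summed. One vehicle file repeats 25 lines word for word, and these were counted once, with their sum as an alternative chosen after seeing the data. Genes with a mean of at least 1 FPKM over the 6 libraries of an experiment were tested on log2(FPKM + 1) without further scaling. Each experiment was fitted alone in limma with group as the only factor, 3 residual degrees of freedom and an eBayes trend, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Replicate numbers do not pair the libraries. With 2 libraries in each group an exact permutation p cannot go below 0.333, so none was computed.

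Gene lists were tested with camera in limma at a preset correlation of 0.01 and with an estimated correlation, for lists with at least 5 tested members. The 29 lists covered stem and progenitor, differentiating spermatogonia, RA response, synaptonemal and cohesin, recombination, piRNA and germ granule, pachytene and spermatid genes, genes of Sertoli, Leydig, peritubular and fibroblast, macrophage and endothelial cells, and immediate early, p53, integrated stress response, DNA replication, G2 and mitosis, cholesterol, glycolysis, ERK feedback, DNA methylation, ribosomal protein, Hox, Rhox, histone, oxidative phosphorylation, proteasome and Wnt genes. Of these, 26 could be tested in each comparison. The lists, the designs, the alternatives and the rule for named genes were written before the data were examined. Lists of ER stress, heat shock, imprinted and NF-kB and chemokine genes were chosen after seeing the data. Chromosomes were taken by gene symbol from an annotation of GRCm38, which held 99.1% of the 22549 symbols.

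Genes named for a comparison were the 3 highest and 3 lowest called changes with a mean of at least 5 FPKM and no overlap between groups, up to 2 rising and 2 falling called members of each described list or else its most abundant member, and 15 genes named whatever their values. Small RNA genes and unnamed gene models were left out of the first of these. On data with simulated changes, limma recovered 100 of 100 genes changed by a log2 of 1 in each treatment comparison, and 68, 66 and 80 of 100 in idSG against mSSC, iSC against idSG and iSC against mSSC. At a log2 of 2 it recovered 99 in iSC against mSSC and 100 elsewhere. False calls were 7.0%, 7.8%, 5.2%, 11.1%, 4.0% and 6.3% of calls over the 6 comparisons. In RA against vehicle, camera at the preset correlation called 5 of 5 lists shifted by 0.3 and 0 of 25 unshifted lists. Correlated lists were not simulated.

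The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean of 5 FPKM, small RNA genes left out, the highest copy of a symbol kept, eBayes without trend, a replicate block, median-ratio scaling, quantile normalization, a least absolute log2 change of 1, the estimated correlation, counting by sign, a fit on all 12 libraries, a fit on the 2 groups alone, and leaving out each replicate. A Sertoli marker score as covariate, and RA and RA with CHX each set against a different vehicle library, were added after seeing the data. Cycloheximide alone was not among the groups.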

Results

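The 12 RNA-seq libraries came from mouse spermatogonial stem cells (mSSC), the germ-line stem cells of the testis, taken from DBA/C57 F1 mice aged 5 to 7 days. In the treatment experiment, mSSC on laminin received vehicle, 100 nM retinoic acid (RA) or 100 nM RA with 0.25 mg/ml cycloheximide (CHX), an inhibitor of protein synthesis, for 24 h. In the induction experiment, untreated mSSC were compared with cells induced on mitomycin-inactivated Sertoli cells from pups, the supporting cells of the seminiferous tubule. GFP-positive, c-KIT-positive cells sorted on day 3 were called induced differentiating spermatogonia (idSG), and GFP-positive, c-KIT-negative cells sorted on day 6 were called induced spermatocytes (iSC). Each of the 6 groups held 2 biological replicates, so every mean ± SD is over n = 2 libraries, and p-values measure only the spread between these samples. The deposited FPKM summed to between 459580 and 540064 per library, and between 11872 and 12510 genes reached 1 FPKM. Log2 values of the 2 replicates correlated across genes at r = 0.994 for vehicle, 0.989 for RA, 0.985 for RA with CHX, 0.984 for mSSC, 0.973 for idSG and 0.963 for iSC, where genes are not independent replicates. The number of genes more than 2-fold apart between replicates was 20, 22, 36, 236, 439 and 491 in the same order. Small RNA genes held 5.07% to 9.75% of the FPKM sum in the treatment libraries and 0.347% to 1.56% in the induction libraries, and the 2 experiments were tested apart.

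**Figure D1:**
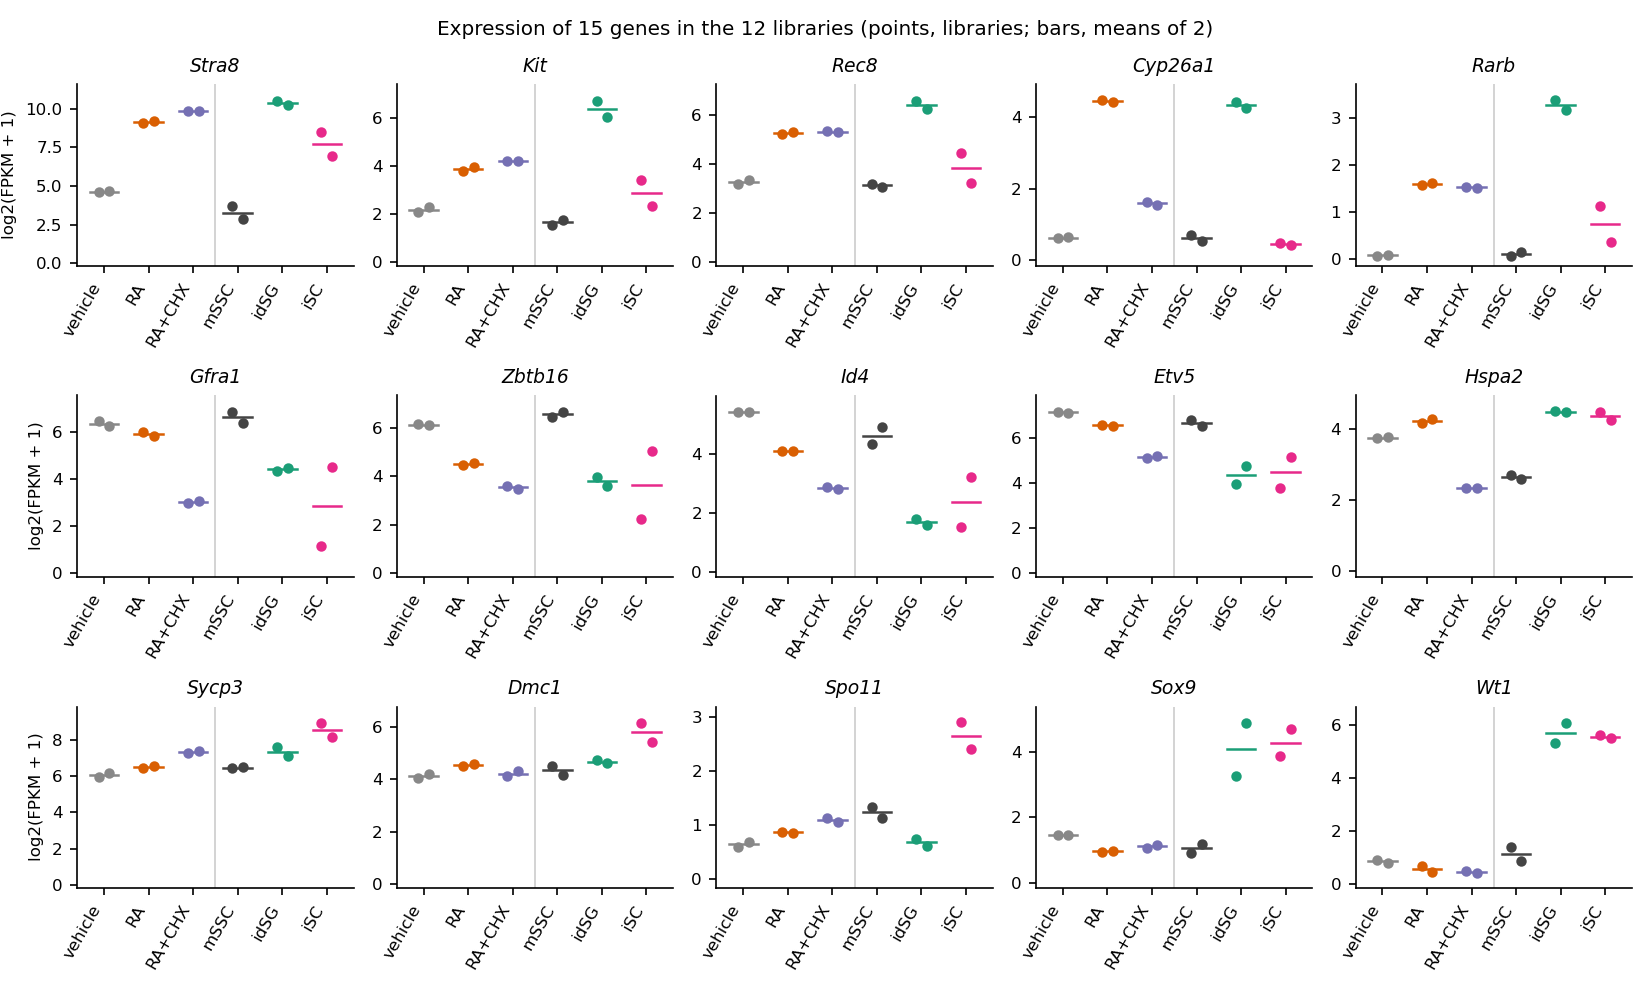
Level of 15 genes, as log2(FPKM + 1) on the vertical axes, in the 6 groups on the horizontal axes, with points for the libraries and bars for the mean of 2. The mean of Stra8 was 23.6 FPKM with vehicle, 561 with RA and 1320.2 in idSG.

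RA, the vitamin A metabolite that starts spermatogonial differentiation, was set against vehicle to ask which transcripts respond within 24 h. Stra8, which is needed for entry into meiosis, rose from 23.6 ± 0.999 to 561 ± 33.2 FPKM (log2 fold change 4.51 ± 0.05 SE, adjusted p = 5.73e-08). Cyp26a1, which encodes an RA-degrading enzyme, rose from 0.544 ± 0.0194 to 20.9 ± 0.372 FPKM and the meiotic cohesin gene Rec8 rose from 8.67 ± 0.744 to 37.5 ± 1.06 FPKM. Kit, the receptor gene that marks differentiating spermatogonia, rose from 3.53 ± 0.479 to 13.8 ± 1.13 FPKM, and the RA receptor gene Rarb rose from 0.0495 ± 0.00786 to 2.02 ± 0.0705 FPKM. The stem cell transcription factor genes Zbtb16 and Id4 fell from 69.4 ± 2.23 to 21.8 ± 0.637 FPKM and from 42.5 ± 0.231 to 16.3 ± 0.136 FPKM. Gfra1, the co-receptor gene for GDNF, fell from 80.2 ± 6.84 to 58.6 ± 4.87 FPKM. Etv5, a target of GDNF and FGF signalling, fell from 138 ± 3.51 to 92.5 ± 1.31 FPKM.

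Limma called 6503 of 12339 genes, 2815 higher and 3688 lower with RA, at a median absolute log2 fold change of 0.29. Of these, 42 genes were higher and 129 lower by at least 2-fold. Agpat3, an acyltransferase gene of phospholipid synthesis, rose from 1.28 ± 0.169 to 21.4 ± 1.43 FPKM. The forkhead genes Foxc2 and Foxf1a fell from 45.4 ± 1.52 to 8.05 ± 0.211 FPKM and from 30.7 ± 0.0497 to 4.93 ± 0.223 FPKM. Among spermatogonial stem and progenitor genes, 0 of 28 rose and 24 fell, with 4 not called (the same counts adjusted over the list alone). Stem and progenitor genes had a median log2 change of -0.60 (camera adjusted p = 1.17e-08, adjusted p = 0.162 with an estimated correlation). Nanos2 fell from 7.97 ± 0.139 to 0.68 ± 0.244 FPKM and Nanos3 from 13.8 ± 0.562 to 2.41 ± 0.624 FPKM, both RNA-binding repressors that keep germ cells undifferentiated. Among RA response genes, 8 of 15 rose and 3 fell, with 4 not called (the same counts adjusted over the list alone). RA response genes had a median log2 change of 0.22 (camera adjusted p = 0.0196, adjusted p = 0.338 with an estimated correlation). Among members that fell were the receptor genes Rarg, from 21.9 ± 1.33 to 10.6 ± 0.404 FPKM, and Rxra, from 32 ± 0.362 to 20.5 ± 0.317 FPKM. Genes of differentiating spermatogonia went both ways, as 6 of 14 rose and 4 fell, with 4 not called (the same counts adjusted over the list alone, camera adjusted p = 0.465), with Ccnd2 falling from 246 ± 13.8 to 141 ± 1.06 FPKM and Dmrtb1 from 16.7 ± 0.437 to 9.41 ± 0.571 FPKM.

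Meiotic genes were called in part. Of synaptonemal complex and meiotic cohesin genes, 4 of 15 rose and 2 fell, with 9 not called (the same counts adjusted over the list alone, camera adjusted p = 0.27). Of meiotic recombination genes, 6 of 24 rose and 4 fell, with 14 not called (the same counts adjusted over the list alone, camera adjusted p = 0.113). Sycp3, of the synaptonemal axis, rose from 65.1 ± 6.93 to 89.1 ± 4.49 FPKM, Dmc1, the meiotic strand-exchange gene, from 16.6 ± 1.13 to 22.3 ± 0.859 FPKM, and Prdm9, which sets recombination sites, from 1.0 ± 0.149 to 2.87 ± 0.151 FPKM. The testis chaperone gene Hspa2 rose from 12.5 ± 0.364 to 17.7 ± 1.08 FPKM. Spo11 stood at 0.564 ± 0.0631 FPKM with vehicle and 0.82 ± 0.0244 with RA, below the level tested. Of pachytene spermatocyte genes, 8 of 19 rose and 3 fell, with 8 not called (9 and 3 adjusted over the list alone), with Clgn rising from 6.99 ± 0.188 to 13.5 ± 0.496 FPKM. Pachytene genes had a median log2 change of 0.15 (camera adjusted p = 0.0475, adjusted p = 0.338 with an estimated correlation). Of piRNA pathway and germ granule genes, 3 of 21 rose and 11 fell, with 7 not called (4 and 11 adjusted over the list alone), with Tdrd5 falling from 57.1 ± 0.944 to 33 ± 0.895 FPKM. Germ granule genes had a median log2 change of -0.12 (camera adjusted p = 0.0475, adjusted p = 0.387 with an estimated correlation).

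Of ERK feedback genes, 0 of 12 rose and 11 fell, with 1 not called (the same counts adjusted over the list alone), and Dusp4, an ERK phosphatase gene, fell from 66.3 ± 5.88 to 33.3 ± 0.615 FPKM. ERK feedback genes had a median log2 change of -0.53 (camera adjusted p = 2.3e-05, adjusted p = 0.338 with an estimated correlation). Of cholesterol synthesis genes, 0 of 20 rose and 15 fell, with 5 not called (0 and 16 adjusted over the list alone), with Fdps falling from 213 ± 2.72 to 127 ± 2.09 FPKM. Cholesterol synthesis genes had a median log2 change of -0.35 (camera adjusted p = 4.39e-05, adjusted p = 0.387 with an estimated correlation). Of glycolysis genes, 1 of 18 rose and 12 fell, with 5 not called (the same counts adjusted over the list alone), and Ldha fell from 45.7 ± 0.13 to 26.9 ± 0.247 FPKM. Glycolysis genes had a median log2 change of -0.31 (camera adjusted p = 0.000868, adjusted p = 0.338 with an estimated correlation). Of integrated stress response genes, 1 of 19 rose and 14 fell, with 4 not called (the same counts adjusted over the list alone), among them Phgdh of serine synthesis, which fell from 231 ± 2.08 to 119 ± 6.9 FPKM. Stress response genes had a median log2 change of -0.30 (camera adjusted p = 0.000264, adjusted p = 0.338 with an estimated correlation). Of proteasome genes, 0 of 37 rose and 27 fell, with 10 not called (0 and 28 adjusted over the list alone). Proteasome genes had a median log2 change of -0.21 (camera adjusted p = 2.3e-05, adjusted p = 0.484 with an estimated correlation). Of the X-linked homeobox Rhox genes, 12 of 19 rose and 0 fell, with 7 not called (14 and 0 adjusted over the list alone), and Rhox3a and Rhox3e, near-identical copies whose levels are uncertain, rose from 1.44 ± 0.234 to 2.87 ± 0.156 FPKM and from 1.12 ± 0.0765 to 2.12 ± 0.324 FPKM. Rhox genes had a median log2 change of 0.26 (camera adjusted p = 0.000102, adjusted p = 0.338 with an estimated correlation).

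Cytosolic ribosomal protein genes fell in the deposited values, where 0 of 78 rose and 68 fell, with 10 not called (0 and 69 adjusted over the list alone), but after quantile normalization 6 rose and 13 fell. Ribosomal protein genes had a median log2 change of -0.26 (camera adjusted p = 2.35e-11, adjusted p = 0.387 with an estimated correlation). The ribosomal protein gene Rps27, whose many processed pseudogenes make it uncertain, fell from 103 ± 27.6 to 20.8 ± 23.9 FPKM with replicates far apart, and lost its call without vehicle replicate 1 (adjusted p = 0.0626) or replicate 2 (adjusted p = 0.102). Of DNA replication genes, 2 of 27 rose and 13 fell, with 12 not called (2 and 15 adjusted over the list alone), and their median became 0.0032 after quantile normalization. Replication genes had a median log2 change of -0.10 (camera adjusted p = 0.00884, adjusted p = 0.387 with an estimated correlation). Of G2 and mitosis genes, 0 of 25 rose and 13 fell, with 12 not called (the same counts adjusted over the list alone), but after quantile normalization 4 rose and 3 fell. Mitotic genes had a median log2 change of -0.12 (camera adjusted p = 0.0468, adjusted p = 0.387 with an estimated correlation). The spermatid, p53 target (2 of 20 rose and 10 fell), Wnt, DNA methylation, Hox, immediate early and histone lists were not called. Oxidative phosphorylation genes were not called as a list in the deposited values, where 8 of 79 rose and 14 fell, with 57 not called (8 and 9 adjusted over the list alone, camera adjusted p = 0.344), but after quantile normalization 26 rose and 3 fell (camera adjusted p = 0.0104).

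The mean log2(FPKM + 1) of the Sertoli cell list was 0.947 and 0.941 in the vehicle libraries and 0.916 and 0.908 with RA, and 1 of 8 rose and 2 fell, with 5 not called (the same counts adjusted over the list alone, camera adjusted p = 0.722). Sox9 fell from 1.75 ± 0.0184 to 0.957 ± 0.0309 FPKM, and Wt1 stood at 0.797 ± 0.0935 and 0.473 ± 0.187 FPKM. The mean of the peritubular and fibroblast list was 2.79 and 2.58 with vehicle and 2.84 and 2.64 with RA, and 2 of 14 rose and 1 fell, with 11 not called (the same counts adjusted over the list alone, camera adjusted p = 0.563). Too few genes of the Leydig cell, macrophage and endothelial lists were expressed for the list test. The Leydig gene Star stood at 1.76 ± 0.168 and 1.68 ± 0.171 FPKM, 1 of 2 macrophage genes fell and 2 of 3 endothelial genes fell, with the same counts adjusted over the list alone, among them Vwf, from 1.74 ± 0.00888 to 0.747 ± 0.0194 FPKM.

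The share of calls that were higher with RA was 43.3% in the deposited values and 55.2% after quantile normalization, which also ended the camera calls of the RA response (adjusted p = 0.083, median 0.33), piRNA (0.387, median -0.0051), pachytene (0.111, median 0.19), DNA replication (0.295), G2 (0.783) and ribosomal (0.296) lists. With the spread estimated from all 12 libraries, 418 genes were called. The camera call of the pachytene list was lost without vehicle replicate 1 (adjusted p = 0.0508), RA replicate 2 (0.0634) or either RA and CHX library (0.0527 and 0.0529), that of the G2 list without vehicle replicate 1 (0.109) or RA replicate 1 (0.0702), and that of the piRNA list without vehicle replicate 2 (0.0865), RA replicate 1 (0.0546) or either RA and CHX library (0.0527 and 0.0529).

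**Figure D2:**
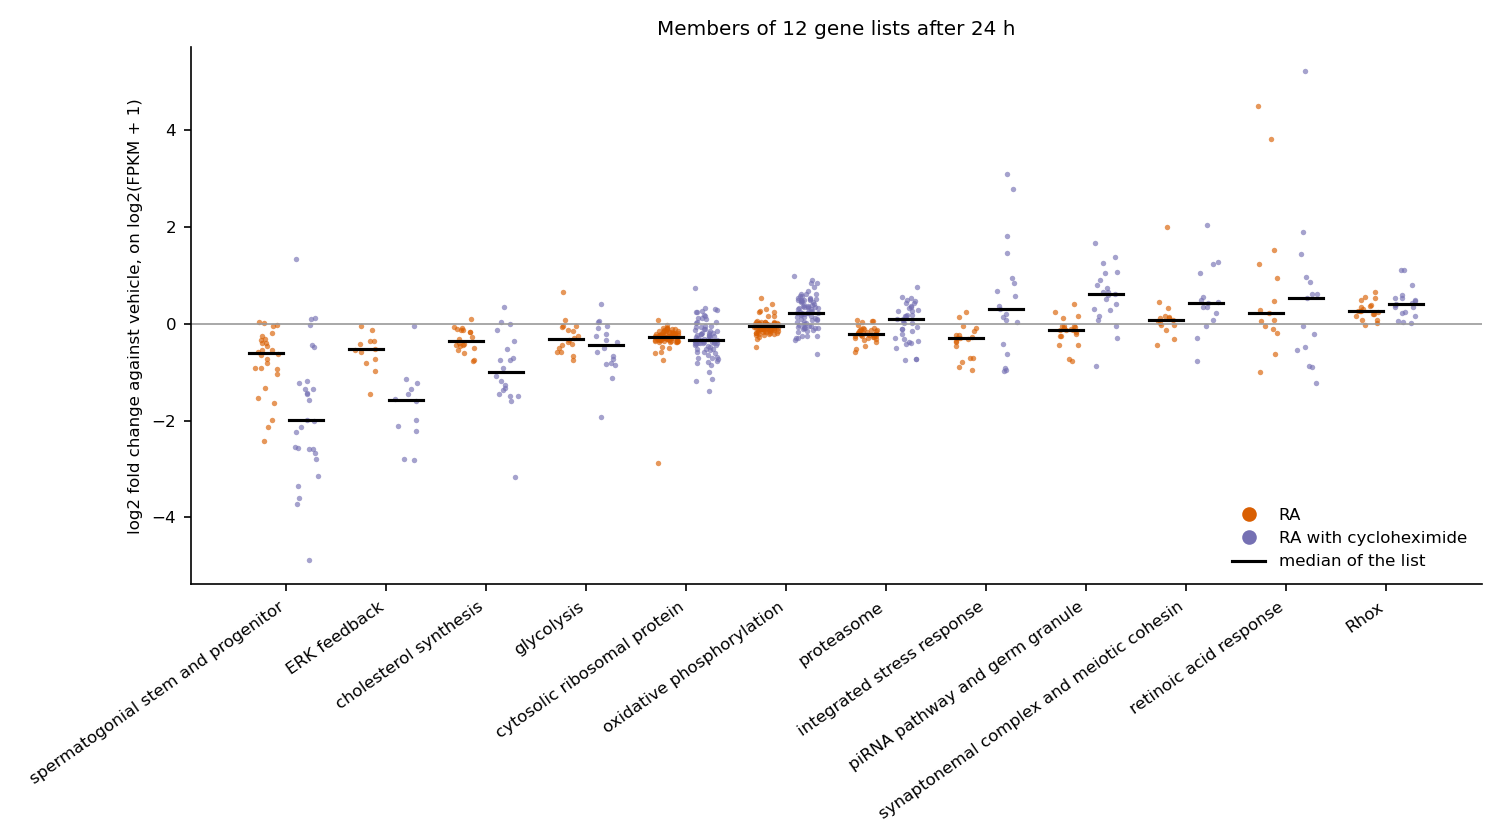
Log2 fold change against vehicle on the log2(FPKM + 1) scale, on the vertical axis, of the members of 12 gene lists on the horizontal axis, with a point for each gene and a line at the list's median. The stem and progenitor median was -0.60 with RA and -2.0 with RA and CHX, and the oxidative phosphorylation median was -0.05 with RA in the deposited values (0.09 after quantile normalization) and 0.23 with RA and CHX.

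RA with CHX was compared with vehicle to ask which changes appear while new protein synthesis is inhibited, although CHX alone was not among the groups. Stra8 rose from 23.6 ± 0.999 to 916 ± 17 FPKM (log2 fold change 5.22 ± 0.05 SE, adjusted p = 7.61e-09) and Rec8 from 8.67 ± 0.744 to 39 ± 0.773 FPKM. Kit rose from 3.53 ± 0.479 to 17.6 ± 0.0784 FPKM, Rarb from 0.0495 ± 0.00786 to 1.86 ± 0.0193 FPKM and Cyp26a1 from 0.544 ± 0.0194 to 2.01 ± 0.128 FPKM. Among stem cell genes, Gfra1 fell from 80.2 ± 6.84 to 7.0 ± 0.392 FPKM, Id4 from 42.5 ± 0.231 to 6.27 ± 0.227 FPKM, Zbtb16 from 69.4 ± 2.23 to 10.7 ± 0.641 FPKM and Etv5 from 138 ± 3.51 to 34.1 ± 1.44 FPKM. Sycp3 rose from 65.1 ± 6.93 to 159 ± 5.97 FPKM, Hspa2 fell from 12.5 ± 0.364 to 4.04 ± 0.0193 FPKM, and Dmc1 stood at 16.6 ± 1.13 and 17.7 ± 1.71 FPKM (adjusted p = 0.326).

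Limma called 9788 of the 12339 genes, 4452 higher and 5336 lower, and 415 and 1143 of them by at least 2-fold, at a median absolute log2 fold change of 0.47. Spp1, which encodes the secreted protein osteopontin, rose from 18.5 ± 5.09 to 213 ± 0.493 FPKM, and the interleukin receptor gene Il1rl1 from 0.884 ± 0.0816 to 17.7 ± 0.421 FPKM. The neurofilament gene Nefm fell from 134 ± 17.4 to 2.87 ± 0.00869 FPKM, Foxc2 from 45.4 ± 1.52 to 1.19 ± 0.0646 FPKM and the LIM homeobox gene Lhx1 from 62.4 ± 0.992 to 1.15 ± 0.0359 FPKM. Of stem and progenitor genes, 2 of 28 rose and 24 fell, with 2 not called (the same counts adjusted over the list alone), and against this Sox3 rose from 39.2 ± 6.66 to 101 ± 4.63 FPKM. Stem and progenitor genes had a median log2 change of -2.0 (camera adjusted p = 4.14e-06, adjusted p = 0.252 with an estimated correlation). Of ERK feedback genes, 0 of 12 rose and 11 fell, with 1 not called (the same counts adjusted over the list alone), with Spry4 falling from 51.9 ± 3.31 to 6.66 ± 0.194 FPKM and Dusp4 from 66.3 ± 5.88 to 8.53 ± 0.322 FPKM. ERK feedback genes had a median log2 change of -1.56 (camera adjusted p = 9.93e-05, adjusted p = 0.559 with an estimated correlation). Of cholesterol synthesis genes, 1 of 20 rose and 17 fell, with 2 not called (the same counts adjusted over the list alone). Cholesterol synthesis genes had a median log2 change of -1.0 (camera adjusted p = 0.000125, adjusted p = 0.559 with an estimated correlation). Of Hox genes, 2 of 10 rose and 8 fell, with 0 not called (the same counts adjusted over the list alone), with Hoxb6 falling from 18.3 ± 1.36 to 1.27 ± 0.101 FPKM. Hox genes had a median log2 change of -1.33 (camera adjusted p = 0.0483, adjusted p = 0.559 with an estimated correlation). Of glycolysis genes, 1 of 18 rose and 13 fell, with 4 not called (the same counts adjusted over the list alone), and Tpi1 fell from 55.4 ± 3.44 to 13.9 ± 0.476 FPKM while Ldha rose from 45.7 ± 0.13 to 61 ± 1.41 FPKM. Glycolysis genes had a median log2 change of -0.43 (camera adjusted p = 0.0217, adjusted p = 0.559 with an estimated correlation).

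Germ granule and meiotic cohesin genes were among those that rose with RA and CHX. Of piRNA pathway and germ granule genes, 17 of 21 rose and 2 fell, with 2 not called (the same counts adjusted over the list alone), with the helicase genes Ddx25 and Mov10l1 rising from 36 ± 0.647 to 116 ± 0.95 FPKM and from 83.2 ± 3.48 to 219.8 ± 1.79 FPKM. Germ granule genes had a median log2 change of 0.62 (camera adjusted p = 0.000125, adjusted p = 0.455 with an estimated correlation). Of synaptonemal complex and cohesin genes, 10 of 15 rose and 2 fell, with 3 not called (the same counts adjusted over the list alone). Synaptonemal and cohesin genes had a median log2 change of 0.44 (camera adjusted p = 0.0183, adjusted p = 0.559 with an estimated correlation). Of meiotic recombination genes, 13 of 24 rose and 8 fell, with 3 not called (the same counts adjusted over the list alone, camera adjusted p = 0.197), with Psmc3ip falling from 32.5 ± 0.291 to 12.6 ± 0.229 FPKM and Prdm9 rising from 1.0 ± 0.149 to 3.19 ± 0.211 FPKM. Of Rhox genes, 15 of 19 rose and 0 fell, with 4 not called (the same counts adjusted over the list alone). Rhox genes had a median log2 change of 0.40 (camera adjusted p = 0.000711, adjusted p = 0.455 with an estimated correlation). Of oxidative phosphorylation genes, 49 of 79 rose and 9 fell, with 21 not called (49 and 8 adjusted over the list alone), and Sdha of complex II rose from 118 ± 3.12 to 237 ± 4.25 FPKM. Oxidative phosphorylation genes had a median log2 change of 0.23 (camera adjusted p = 9.93e-05, adjusted p = 0.564 with an estimated correlation). Of ribosomal protein genes, 10 of 78 rose and 57 fell, with 11 not called (the same counts adjusted over the list alone), with Rps12 falling from 1363 ± 91.9 to 518 ± 24 FPKM and Rpl26 rising from 180.0 ± 1.16 to 301 ± 13.3 FPKM. Ribosomal protein genes had a median log2 change of -0.33 (camera adjusted p = 0.000731, adjusted p = 0.564 with an estimated correlation). Of integrated stress response genes, 12 of 19 rose and 5 fell, with 2 not called (the same counts adjusted over the list alone), and Chac1 and Nupr1 rose from 1.42 ± 0.248 to 19.7 ± 0.298 FPKM and from 1.99 ± 0.0697 to 19.6 ± 0.776 FPKM. Stress response genes had a median log2 change of 0.32 (camera adjusted p = 0.0483, adjusted p = 0.559 with an estimated correlation).

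Of RA response genes, 8 of 15 rose and 6 fell, with 1 not called (the same counts adjusted over the list alone, camera adjusted p = 0.241), with the RA-degrading gene Cyp26b1 rising from 0.10 ± 0.0191 to 3.12 ± 0.309 FPKM and Dhrs3, a retinaldehyde reductase gene, falling from 9.68 ± 0.33 to 3.57 ± 0.169 FPKM. Of differentiating spermatogonia genes, 7 of 14 rose and 7 fell, with 0 not called (the same counts adjusted over the list alone, camera adjusted p = 0.707). Of Sertoli cell genes, 5 of 8 rose and 3 fell, with 0 not called (the same counts adjusted over the list alone, camera adjusted p = 0.268), and the list's mean log2(FPKM + 1) was 1.11 and 1.12 in the RA and CHX libraries. The inhibin subunit gene Inhba rose from 0.416 ± 0.123 to 5.34 ± 0.357 FPKM and the gap junction gene Gja1 from 0.681 ± 0.0908 to 5.36 ± 0.0839 FPKM, whereas Sox9 fell from 1.75 ± 0.0184 to 1.16 ± 0.122 FPKM and Wt1 stood at 0.356 ± 0.0363 FPKM. Of peritubular and fibroblast genes, 7 of 14 rose and 3 fell, with 4 not called (the same counts adjusted over the list alone, camera adjusted p = 0.232), and all 3 tested endothelial genes fell, 3 adjusted over the list alone.

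Quantile normalization shifted the median of all genes by 0.11 here and gave 55.3% of calls as higher in place of 45.5%. With it or with median-ratio scaling the camera calls of the stress response list (adjusted p = 0.183 and 0.0601, medians 0.33 and 0.36) ended, as did those of the synaptonemal (0.0666, median 0.42) and ribosomal (0.288, with 24 rising, 34 falling and a median of -0.096) lists with quantile normalization. The stress response call was also lost without vehicle replicate 1 (0.0648), vehicle replicate 2 (0.0638) or RA and CHX replicate 1 (0.0544), and the Hox call without vehicle replicate 2 (0.126).

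The direct comparison of RA with and without CHX gave the difference itself. Stra8 was higher with CHX, from 561 ± 33.2 to 916 ± 17 FPKM (log2 fold change 0.71 ± 0.05 SE, adjusted p = 1.05e-05), and Cyp26a1 lower, from 20.9 ± 0.372 to 2.01 ± 0.128 FPKM. Gfra1 was lower, from 58.6 ± 4.87 to 7.0 ± 0.392 FPKM, as were Id4, from 16.3 ± 0.136 to 6.27 ± 0.227 FPKM, and Zbtb16, from 21.8 ± 0.637 to 10.7 ± 0.641 FPKM. Rec8 at 37.5 ± 1.06 and 39 ± 0.773 FPKM and Rarb at 2.02 ± 0.0705 and 1.86 ± 0.0193 FPKM were not called (adjusted p = 0.412 and adjusted p = 0.353). The transcriptional repressor gene Bcl6b, a GDNF target, stood at 128 ± 13.9 FPKM with RA and fell to 8.89 ± 0.141 with CHX.

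Limma called 9573 genes, 4332 higher and 5241 lower, of which 333 and 869 by at least 2-fold, at a median absolute log2 fold change of 0.45. Of stem and progenitor genes, 4 of 28 rose and 21 fell, with 3 not called (4 and 22 adjusted over the list alone). Stem and progenitor genes had a median log2 change of -1.12 (camera adjusted p = 0.000775, adjusted p = 0.467 with an estimated correlation). Lhx1 fell from 43 ± 2.47 to 1.15 ± 0.0359 FPKM and the neurexophilin gene Nxph4 from 17.2 ± 2.97 to 0.414 ± 0.0475 FPKM. Of ERK feedback genes, 1 of 12 rose and 11 fell, with 0 not called (the same counts adjusted over the list alone). ERK feedback genes had a median log2 change of -1.24 (camera adjusted p = 0.000879, adjusted p = 0.618 with an estimated correlation). Of cholesterol synthesis genes, 4 of 20 rose and 14 fell, with 2 not called (the same counts adjusted over the list alone). Cholesterol synthesis genes had a median log2 change of -0.71 (camera adjusted p = 0.0139, adjusted p = 0.715 with an estimated correlation). Of Hox genes, 1 of 10 rose and 8 fell, with 1 not called (the same counts adjusted over the list alone). Hox genes had a median log2 change of -1.71 (camera adjusted p = 0.0139, adjusted p = 0.618 with an estimated correlation). Of piRNA and germ granule genes, 17 of 21 rose and 2 fell, with 2 not called (the same counts adjusted over the list alone). Germ granule genes had a median log2 change of 0.65 (camera adjusted p = 1.05e-05, adjusted p = 0.467 with an estimated correlation). Of synaptonemal and cohesin genes, 10 of 15 rose and 1 fell, with 4 not called (the same counts adjusted over the list alone), with Smc1b rising from 91.9 ± 6.76 to 198 ± 23.5 FPKM and Fkbp6 from 153 ± 5.78 to 347 ± 0.108 FPKM. Synaptonemal and cohesin genes had a median log2 change of 0.34 (camera adjusted p = 0.0228, adjusted p = 0.715 with an estimated correlation). Of stress response genes, 14 of 19 rose and 3 fell, with 2 not called (the same counts adjusted over the list alone), and Chac1 rose from 0.968 ± 0.103 to 19.7 ± 0.298 FPKM. Stress response genes had a median log2 change of 0.48 (camera adjusted p = 0.000879, adjusted p = 0.493 with an estimated correlation). Of oxidative phosphorylation genes, 55 of 79 rose and 8 fell, with 16 not called (the same counts adjusted over the list alone). Oxidative phosphorylation genes had a median log2 change of 0.36 (camera adjusted p = 1.05e-05, adjusted p = 0.721 with an estimated correlation). Of proteasome genes, 26 of 37 rose and 7 fell, with 4 not called (the same counts adjusted over the list alone), with Psmd13 rising from 93.8 ± 0.802 to 158 ± 1.93 FPKM. Proteasome genes had a median log2 change of 0.28 (camera adjusted p = 0.00117, adjusted p = 0.742 with an estimated correlation). Uhrf1, which maintains DNA methylation, fell from 278 ± 16 to 107 ± 0.951 FPKM and Sohlh1, a spermatogonial transcription factor gene, rose from 60.6 ± 0.771 to 147 ± 4.12 FPKM. Sertoli cell genes moved too, as 5 of 8 rose and 2 fell, with 1 not called (the same counts adjusted over the list alone, camera adjusted p = 0.17). Kit rose from 13.8 ± 1.13 to 17.6 ± 0.0784 FPKM, and this call was lost without RA replicate 1 (adjusted p = 0.0509). Quantile normalization gave 52.6% of calls as higher in place of 45.3%. It ended the camera calls of the synaptonemal (adjusted p = 0.189, median 0.19), oxidative phosphorylation (0.126, with 41 rising and 22 falling, median 0.18) and proteasome (0.386, with 19 rising and 11 falling, median 0.089) lists. The median, mean and test did not share a sign for the differentiating, RA response, pachytene and immediate early lists, none of which was called.

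Of the 6503 genes called with RA, 59.7% were also called in the same direction against vehicle with RA and CHX, 54.0% of those higher and 64.2% of those lower. Another 1527 were called in the opposite direction against vehicle, 721 of those higher and 806 of those lower with RA. The overlaps were 1519 genes higher and 2366 lower in both, where independent lists would share 1016 and 1595. The direct comparison called 42.8% of the 6503 genes against the RA change and 36.9% further along it. It shares the RA libraries and called 77.6% of all genes, so these shares lack a chance level. Of the 171 genes changed at least 2-fold by RA, 155 were called in the same direction with CHX. Both comparisons shared the 2 vehicle libraries. In 100 simulations of unchanged groups, 23.3% of genes at an unadjusted p under 0.05 were kept (observed 59.1%). The 23.3% is no chance level here, as RA with CHX called 79.3% of genes. Across genes, which are not independent replicates, fold changes correlated at r = 0.46 (simulated 0.48) and 62.3% shared a sign (66.6%). The covariance was 0.139 (0.0082). In a test chosen after the results were seen, RA was set against one vehicle library and RA with CHX against the other, so that no control was shared and each control was a lone library, assumed to vary like the other groups. Of 5461 and 5217 genes then called with RA, 58.0% and 59.0% were called in the same direction with RA and CHX, and 1198 and 1103 in the opposite direction. The fold changes correlated at r = 0.40 and 0.42, with a covariance of 0.126 and 0.129.

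**Figure D3:**
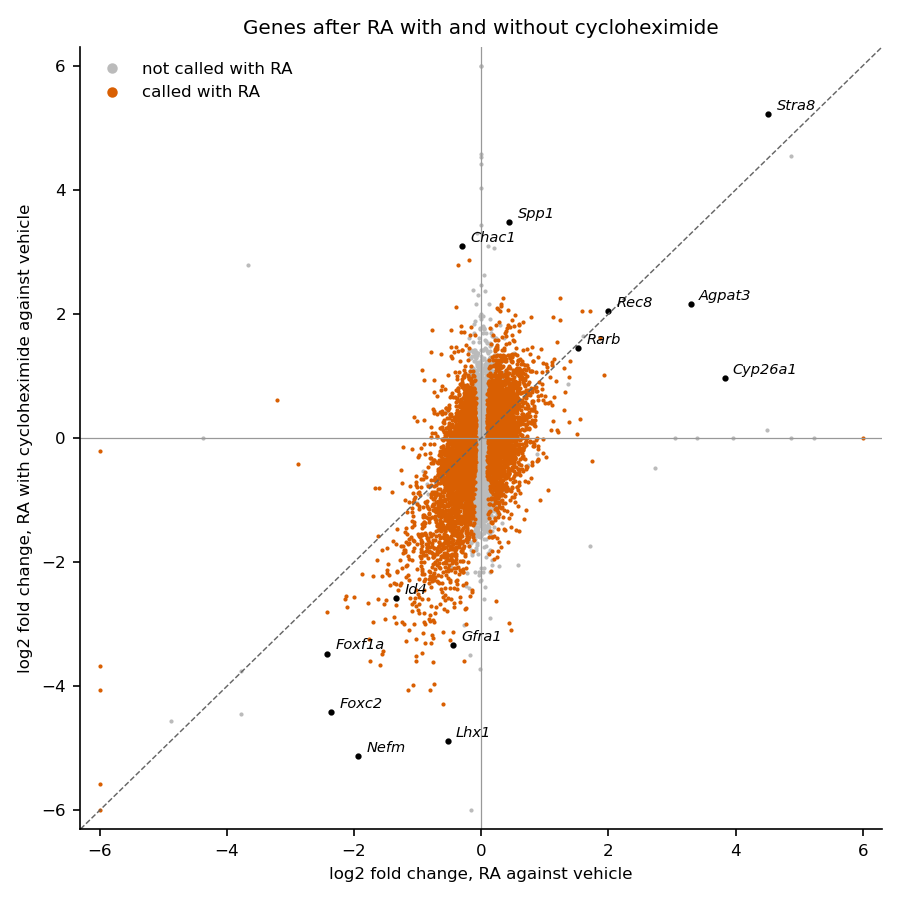
Log2 fold change of each tested gene with RA, on the horizontal axis, against that with RA and CHX, on the vertical axis, both against vehicle on the log2(FPKM + 1) scale, with genes beyond 6 drawn at the edge and the dashed line at equal changes. Stra8 lies at 4.51 and 5.22, Cyp26a1 at 3.82 and 0.96, and Lhx1 at -0.53 and -4.88.

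The induced differentiating spermatogonia were compared with untreated mSSC to describe day 3 of induction. Stra8 rose from 9.0 ± 3.87 to 1320.2 ± 183 FPKM (log2 fold change 7.09 ± 0.49 SE, adjusted p = 0.000661), Rec8 from 7.78 ± 0.455 to 85.2 ± 15.2 FPKM and Rarb from 0.0732 ± 0.0471 to 8.69 ± 0.939 FPKM. Cyp26a1 rose from 0.536 ± 0.119 to 19.1 ± 1.69 FPKM and Hspa2 from 5.28 ± 0.272 to 21.3 ± 0.257 FPKM. Lhx1 fell from 36 ± 4.21 to 0.485 ± 0.116 FPKM and Spry4 from 35.2 ± 9.58 to 2.45 ± 1.07 FPKM, and Id4 fell from 24.1 ± 7.01 to 2.26 ± 0.314 FPKM. Kit, the gene of the protein used to sort these cells, was 2.15 ± 0.376 FPKM in mSSC and 85.6 ± 27.9 in idSG, which checks the gate and is no finding. Genes of Sertoli cells were higher in the same libraries, with Clu, which encodes clusterin, rising from 1.69 ± 0.17 to 517 ± 319 FPKM, Wt1 from 1.21 ± 0.579 to 52.9 ± 19.6 FPKM and Sox9 from 1.08 ± 0.279 to 18.9 ± 14.4 FPKM.

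Limma called 3613 of 12626 genes, 2265 higher and 1348 lower, with 1379 and 546 of them at least 2-fold and a median absolute log2 fold change of 1.05. The glutathione transferase gene Gstm2 rose from 1.37 ± 0.638 to 748 ± 487 FPKM, Aldh1a1, which encodes an RA-synthesising enzyme, from 0.636 ± 0.094 to 458 ± 175 FPKM and Ctgf, a secreted matrix protein gene, from 0.477 ± 0.217 to 288 ± 139 FPKM. Of Sertoli cell genes, 16 of 20 rose and 0 fell, with 4 not called (18 and 0 adjusted over the list alone), and the list's mean log2(FPKM + 1) was 0.877 and 1.02 in mSSC and 3.32 and 4.22 in idSG. Sertoli cell genes had a median log2 change of 3.23 (camera adjusted p = 1.03e-09, adjusted p = 0.97 with an estimated correlation). The Sertoli gene Aard rose from 0.161 ± 0.0916 to 174 ± 122 FPKM. All 3 tested Leydig cell genes rose, 3 adjusted over the list alone, among them Star, from 2.29 ± 0.324 to 52.1 ± 26.2 FPKM. Of peritubular and fibroblast genes, 5 of 15 rose and 5 fell, with 5 not called (the same counts adjusted over the list alone, camera adjusted p = 0.943), with Acta2 rising from 0.693 ± 0.635 to 69.4 ± 28.9 FPKM and Tagln from 1.95 ± 1.19 to 71.3 ± 22.7 FPKM. Of 3 macrophage genes 1 fell (1 adjusted over the list alone), and the single tested endothelial gene, Kdr, stood at 1.23 ± 0.283 and 1.46 ± 0.685 FPKM.

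With the Sertoli list at those levels, 13 of 21 rose and 2 fell, with 6 not called (14 and 3 adjusted over the list alone) among RA response genes, and Stra6, the retinol transporter gene, rose from 0.0107 ± 0.0151 to 65.2 ± 26 FPKM. RA response genes had a median log2 change of 1.62 (camera adjusted p = 0.000175, adjusted p = 0.97 with an estimated correlation). Of immediate early genes, which respond within minutes to stress or growth factors, 16 of 26 rose and 3 fell, with 7 not called (18 and 3 adjusted over the list alone), with Cyr61 rising from 1.34 ± 0.184 to 335 ± 177 FPKM and Egr3 falling from 13.2 ± 2.58 to 1.03 ± 1.15 FPKM. Immediate early genes had a median log2 change of 2.41 (camera adjusted p = 2.06e-05, adjusted p = 0.97 with an estimated correlation). Of p53 target genes, 13 of 22 rose and 1 fell, with 8 not called (16 and 1 adjusted over the list alone), with the cell cycle inhibitor gene Cdkn1a rising from 22.4 ± 12.5 to 247 ± 149.9 FPKM and Gdf15 from 0.272 ± 0.0314 to 26 ± 15 FPKM. p53 target genes had a median log2 change of 1.22 (camera adjusted p = 0.000259, adjusted p = 0.97 with an estimated correlation). Of oxidative phosphorylation genes, 18 of 79 rose and 1 fell, with 60 not called (15 and 1 adjusted over the list alone), with Ndufa1 rising from 64 ± 1.44 to 208 ± 23.4 FPKM. Oxidative phosphorylation genes had a median log2 change of 0.28 (camera adjusted p = 0.00118, adjusted p = 0.97 with an estimated correlation). Of Rhox genes, 5 of 20 rose and 0 fell, with 15 not called (6 and 0 adjusted over the list alone), with Rhox10 rising from 4.95 ± 0.29 to 26.6 ± 6.5 FPKM. Rhox genes had a median log2 change of 0.54 (camera adjusted p = 0.0163, adjusted p = 0.97 with an estimated correlation).

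Of stem and progenitor genes, 0 of 27 rose and 16 fell, with 11 not called (0 and 18 adjusted over the list alone), and Gfra1 stood at 98 ± 22.5 and 20 ± 1.28 FPKM (adjusted p = 0.115), a gene that was called without iSC replicate 1 or 2 (adjusted p = 0.00267 and 0.00260). Stem and progenitor genes had a median log2 change of -1.35 (camera adjusted p = 5.58e-08, adjusted p = 0.97 with an estimated correlation). Zbtb16 fell from 94.8 ± 9.53 to 13 ± 2.69 FPKM and Etv5 from 100.2 ± 12.2 to 20.2 ± 7.97 FPKM. Of ERK feedback genes, 0 of 12 rose and 5 fell, with 7 not called (0 and 6 adjusted over the list alone). ERK feedback genes had a median log2 change of -0.71 (camera adjusted p = 0.00517, adjusted p = 0.97 with an estimated correlation). Of cholesterol synthesis genes, 0 of 20 rose and 8 fell, with 12 not called (0 and 10 adjusted over the list alone). Cholesterol synthesis genes had a median log2 change of -0.57 (camera adjusted p = 1.74e-05, adjusted p = 0.97 with an estimated correlation). Of Hox genes, 0 of 10 rose and 3 fell, with 7 not called (0 and 5 adjusted over the list alone). Hox genes had a median log2 change of -1.01 (camera adjusted p = 0.0252, adjusted p = 0.97 with an estimated correlation). Of G2 and mitosis genes, 0 of 25 rose and 3 fell, with 22 not called (0 and 1 adjusted over the list alone). Mitotic genes had a median log2 change of -0.30 (camera adjusted p = 0.00134, adjusted p = 0.97 with an estimated correlation). Of differentiating spermatogonia genes, 5 of 14 rose and 2 fell, with 7 not called (5 and 3 adjusted over the list alone, camera adjusted p = 0.401), with Ccnd2 falling from 161 ± 34.9 to 52.2 ± 14.1 FPKM. Of synaptonemal and cohesin genes, 4 of 15 rose and 1 fell, with 10 not called (5 and 1 adjusted over the list alone, camera adjusted p = 0.132). Of recombination genes, 2 of 26 rose and 0 fell, with 24 not called (1 and 0 adjusted over the list alone, camera adjusted p = 0.943). Sycp3 stood at 87.4 ± 1.39 and 165 ± 42.6 FPKM (adjusted p = 0.0556), and was called without iSC replicate 1 or 2 (adjusted p = 0.0235 and 0.0229). Dmc1 at 19.5 ± 3.65 and 24.6 ± 1.53 FPKM (adjusted p = 0.357) and Spo11 at 1.36 ± 0.224 and 0.606 ± 0.0943 FPKM (adjusted p = 0.129) were not called. No single ribosomal protein gene was called in limma, though the list as a whole was lower, as 0 of 78 rose and 0 fell, with 78 not called (the same counts adjusted over the list alone). Ribosomal protein genes had a median log2 change of -0.16 (camera adjusted p = 0.0456, adjusted p = 0.97 with an estimated correlation).

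Zbtb16 lost its call without mSSC replicate 1 (adjusted p = 0.124), mSSC replicate 2 (0.133), idSG replicate 1 (0.114) or idSG replicate 2 (0.172), Id4 without mSSC replicate 2 (0.0518) or idSG replicate 2 (0.0678), and Etv5 without mSSC replicate 1 (0.0698) or idSG replicate 1 (0.0694). The count of called genes was 961 and 1342 without mSSC replicates 1 and 2, and 2358 and 1305 without idSG replicates 1 and 2. The list calls lost were those of the ribosomal list without mSSC replicate 2 (0.154) or idSG replicate 2 (0.708), the Hox list without the same libraries (0.0592 and 0.121), the Rhox list without mSSC replicate 2 (0.0560) or idSG replicate 1 (0.243), and the ERK and oxidative phosphorylation lists without idSG replicate 1 (0.198 and 0.0821). Quantile normalization shifted the median of all genes by -0.11, gave 47.8% of calls as higher in place of 62.7%, ended the ribosomal call (0.244, median -0.11), and turned the medians of the recombination and the peritubular and fibroblast lists from 0.06 to -0.17 and from 0.22 to -0.09.

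The iSC libraries were compared with idSG to describe the step to day 6. Prdm9 rose from 3.87 ± 0.0948 to 42.5 ± 16.9 FPKM (log2 fold change 3.10 ± 0.28 SE, adjusted p = 0.00708) and Hfm1, a meiotic helicase gene, from 2.04 ± 0.0548 to 22 ± 7.1 FPKM. Rad21l, of the meiotic cohesin, rose from 6.36 ± 0.506 to 31.2 ± 3.79 FPKM, Spo11, which makes meiotic double-strand breaks, from 0.606 ± 0.0943 to 5.36 ± 1.53 FPKM and Dmc1 from 24.6 ± 1.53 to 57.1 ± 20.5 FPKM. Sycp3 rose from 165 ± 42.6 to 387 ± 146 FPKM and Tex12, of the synaptonemal central element, from 33.3 ± 9.52 to 139.7 ± 48.2 FPKM. Stra8 fell from 1320.2 ± 183 to 239.8 ± 168 FPKM, Rec8 from 85.2 ± 15.2 to 14.7 ± 8.95 FPKM, Rarb from 8.69 ± 0.939 to 0.718 ± 0.625 FPKM and Cyp26a1 from 19.1 ± 1.69 to 0.367 ± 0.0277 FPKM. Kit, which sorted both groups, was 85.6 ± 27.9 FPKM in idSG and 6.89 ± 4.04 in iSC.

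Limma called 1415 of the 12626 genes, 563 higher and 852 lower, with 314 and 244 of them at least 2-fold and a median absolute log2 fold change of 0.90. The Wnt inhibitor gene Sfrp4 rose from 14.9 ± 2.72 to 226 ± 74 FPKM, the teneurin gene Odz4 from 0.642 ± 0.0631 to 18.5 ± 5.24 FPKM and the chemokine gene Cxcl5 from 1.09 ± 0.289 to 29 ± 3.25 FPKM. Of synaptonemal and cohesin genes, 8 of 15 rose and 1 fell, with 6 not called (9 and 2 adjusted over the list alone). Synaptonemal and cohesin genes had a median log2 change of 0.95 (camera adjusted p = 0.00128, adjusted p = 0.878 with an estimated correlation). Of recombination genes, 8 of 26 rose and 1 fell, with 17 not called (12 and 5 adjusted over the list alone). Meiotic recombination genes had a median log2 change of 0.40 (camera adjusted p = 0.000964, adjusted p = 0.878 with an estimated correlation). Of differentiating spermatogonia genes, 1 of 14 rose and 6 fell, with 7 not called (1 and 9 adjusted over the list alone), with Ccnd2 rising from 52.2 ± 14.1 to 100.2 ± 13.1 FPKM. Differentiating spermatogonia genes had a median log2 change of -1.10 (camera adjusted p = 0.00124, adjusted p = 0.878 with an estimated correlation). Of DNA replication genes, 1 of 27 rose and 12 fell, with 14 not called (1 and 16 adjusted over the list alone), with Mcm2 of the replicative helicase falling from 132 ± 20 to 57.1 ± 8.57 FPKM. Replication genes had a median log2 change of -0.55 (camera adjusted p = 8.86e-05, adjusted p = 0.878 with an estimated correlation). Of RA response genes, 2 of 21 rose and 4 fell, with 15 not called (4 and 8 adjusted over the list alone, camera adjusted p = 0.28). Of stem and progenitor genes, 1 of 27 rose and 1 fell, with 25 not called (0 and 0 adjusted over the list alone, camera adjusted p = 0.572). Zbtb16 stood at 13 ± 2.69 and 18 ± 20.1 FPKM, Gfra1 at 20 ± 1.28 and 11.5 ± 14.5 and Id4 at 2.26 ± 0.314 and 5.17 ± 4.65, none of them called.

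Sertoli cell genes were higher again as a list, where 1 of 20 rose and 0 fell, with 19 not called (6 and 0 adjusted over the list alone), with list means of 3.32 and 4.22 in idSG and 4.14 and 4.46 in iSC. Sertoli cell genes had a median log2 change of 0.71 (camera adjusted p = 0.00156, adjusted p = 0.878 with an estimated correlation). Clu rose from 517 ± 319 to 1661 ± 636 FPKM, while Sox9 at 18.9 ± 14.4 and 19.5 ± 8.21 FPKM and Wt1 at 52.9 ± 19.6 and 45.7 ± 2.71 were not called. Of peritubular and fibroblast genes, 1 of 15 rose and 0 fell, with 14 not called (4 and 0 adjusted over the list alone), with Cnn1 rising from 0.982 ± 0.167 to 3.88 ± 0.71 FPKM. Peritubular and fibroblast genes had a median log2 change of 0.62 (camera adjusted p = 0.0093, adjusted p = 0.878 with an estimated correlation). Of 3 Leydig genes 1 rose (2 adjusted over the list alone), Cyp11a1, from 1.76 ± 0.808 to 5.42 ± 1.9 FPKM. Lyz2 of the macrophage list stood at 13.8 ± 14.4 and 12.2 ± 1.07 FPKM and Kdr of the endothelial list at 1.46 ± 0.685 and 1.01 ± 0.90. Of immediate early genes, 1 of 26 rose and 0 fell, with 25 not called (0 and 0 adjusted over the list alone), with Nr4a1 rising from 35.8 ± 8.92 to 73.2 ± 18 FPKM. Immediate early genes had a median log2 change of 0.64 (camera adjusted p = 0.00644, adjusted p = 0.878 with an estimated correlation). Of Hox genes, 0 of 10 rose and 0 fell, with 10 not called (0 and 4 adjusted over the list alone). Hox genes had a median log2 change of -0.95 (camera adjusted p = 0.00644, adjusted p = 0.878 with an estimated correlation). Of ribosomal protein genes, 0 of 78 rose and 1 fell, with 77 not called (the same counts adjusted over the list alone). Ribosomal protein genes had a median log2 change of -0.23 (camera adjusted p = 0.0271, adjusted p = 0.878 with an estimated correlation). Of oxidative phosphorylation genes, 0 of 79 rose and 7 fell, with 72 not called (the same counts adjusted over the list alone). Oxidative phosphorylation genes had a median log2 change of -0.23 (camera adjusted p = 0.00505, adjusted p = 0.878 with an estimated correlation). Of proteasome genes, 0 of 38 rose and 2 fell, with 36 not called (0 and 0 adjusted over the list alone). Proteasome genes had a median log2 change of -0.28 (camera adjusted p = 0.00517, adjusted p = 0.878 with an estimated correlation).

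Leaving out idSG replicate 1 left 8 called genes, and 31 of the 34 called named genes lost their calls without it, at adjusted p from 0.0526 for Sfrp4 to 0.220 for Cyp11a1. The exceptions were Cyp26a1, Rps27 and Hist1h2ao. Leaving out mSSC replicate 1, mSSC replicate 2, idSG replicate 2 or iSC replicate 1 left 208, 152, 911 or 141 genes and ended 17, 19, 11 or 21 of the 34 calls, against 8 for iSC replicate 2. Without iSC replicate 2, Gfra1 (adjusted p = 0.0128) and Zbtb16 (0.0269) were called. The list calls lost were those of the ribosomal list without mSSC replicate 2 (0.0512), idSG replicate 1 (0.674) or iSC replicate 1 (0.374, with the direction turned upward), the Sertoli list without idSG replicate 1 (0.226), the immediate early list without idSG replicate 1 (0.226) or iSC replicate 2 (0.771), the Hox list without idSG replicate 1 (0.0850) or iSC replicate 1 (0.0605), the oxidative phosphorylation list without idSG replicate 1 (0.271), the proteasome list without idSG replicate 1 (0.120) or iSC replicate 1 (0.107), and the peritubular and fibroblast list without idSG replicate 2 (0.152). Quantile normalization ended the calls of the ribosomal (0.119, median -0.10) and oxidative phosphorylation (0.0987, median -0.13) lists, and median-ratio scaling gave 53.1% of called genes as higher in place of 39.8%. For the uncalled stem, spermatid and histone lists the median, mean and test did not share a sign.

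Against untreated mSSC, iSC showed the whole course. Prdm9 rose from 0.916 ± 0.0832 to 42.5 ± 16.9 FPKM (log2 fold change 4.45 ± 0.28 SE, adjusted p = 0.000254), Spata22 from 1.61 ± 0.106 to 35 ± 14.4 FPKM and Hormad1, of the unsynapsed axis, from 18.1 ± 0.146 to 154 ± 52.6 FPKM. Sycp3 rose from 87.4 ± 1.39 to 387 ± 146 FPKM, Dmc1 from 19.5 ± 3.65 to 57.1 ± 20.5 FPKM, Spo11 from 1.36 ± 0.224 to 5.36 ± 1.53 FPKM and Hspa2 from 5.28 ± 0.272 to 19.5 ± 2.19 FPKM. Stra8 rose from 9.0 ± 3.87 to 239.8 ± 168 FPKM, whereas Rec8 at 7.78 ± 0.455 and 14.7 ± 8.95 FPKM and Rarb at 0.0732 ± 0.0471 and 0.718 ± 0.625 were not called. Lhx1 fell from 36 ± 4.21 to 1.61 ± 2.14 FPKM, Etv5 from 100.2 ± 12.2 to 23.8 ± 15.5 FPKM and Gfra1 from 98 ± 22.5 to 11.5 ± 14.5 FPKM. In the same libraries Clu rose from 1.69 ± 0.17 to 1661 ± 636 FPKM and Inha, of the Sertoli hormone inhibin, from 0.591 ± 0.026 to 444 ± 166 FPKM.

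Limma called 6461 genes, 3309 higher and 3152 lower, with 2040 and 1152 of them at least 2-fold and a median absolute log2 fold change of 0.99. Aldh1a1 rose from 0.636 ± 0.094 to 813 ± 39.3 FPKM and the homeobox gene Barhl2 fell from 29.6 ± 17.1 to 0.433 ± 0.449 FPKM. Of synaptonemal and cohesin genes, 10 of 15 rose and 2 fell, with 3 not called (the same counts adjusted over the list alone). Synaptonemal and cohesin genes had a median log2 change of 1.26 (camera adjusted p = 0.00163, adjusted p = 0.844 with an estimated correlation). Of recombination genes, 16 of 26 rose and 4 fell, with 6 not called (the same counts adjusted over the list alone), with Trip13 falling from 46.6 ± 4.32 to 22 ± 2.68 FPKM. Meiotic recombination genes had a median log2 change of 0.67 (camera adjusted p = 0.0079, adjusted p = 0.844 with an estimated correlation). Of stem and progenitor genes, 1 of 27 rose and 20 fell, with 6 not called (1 and 21 adjusted over the list alone), with Shisa6 rising from 1.15 ± 0.348 to 6.91 ± 2.0 FPKM. Stem and progenitor genes had a median log2 change of -1.86 (camera adjusted p = 0.000169, adjusted p = 0.844 with an estimated correlation). Of RA response genes, 12 of 21 rose and 3 fell, with 6 not called (the same counts adjusted over the list alone), with Rarres2 rising from 0.109 ± 0.154 to 29.4 ± 11.8 FPKM. RA response genes had a median log2 change of 0.79 (camera adjusted p = 0.0214, adjusted p = 0.844 with an estimated correlation). Of differentiating spermatogonia genes, 4 of 14 rose and 6 fell, with 4 not called (the same counts adjusted over the list alone, camera adjusted p = 0.245), with Dmrt1 falling from 226 ± 22.4 to 76 ± 12.9 FPKM. Of piRNA and germ granule genes, 1 of 21 rose and 12 fell, with 8 not called (2 and 12 adjusted over the list alone), with Tdrd1 falling from 52.4 ± 3.61 to 16.6 ± 5.58 FPKM and Mybl1, a pachytene transcription factor gene, rising from 0.816 ± 0.161 to 15.9 ± 4.59 FPKM. Germ granule genes had a median log2 change of -0.69 (camera adjusted p = 0.0371, adjusted p = 0.844 with an estimated correlation).

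Of Sertoli cell genes, 19 of 20 rose and 0 fell, with 1 not called (the same counts adjusted over the list alone), with Sox9 rising from 1.08 ± 0.279 to 19.5 ± 8.21 FPKM and Wt1 from 1.21 ± 0.579 to 45.7 ± 2.71 FPKM. Sertoli cell genes had a median log2 change of 4.14 (camera adjusted p = 2.06e-09, adjusted p = 0.844 with an estimated correlation). All 3 Leydig genes rose, 3 adjusted over the list alone, with Star rising from 2.29 ± 0.324 to 117 ± 33.8 FPKM. Of peritubular and fibroblast genes, 8 of 15 rose and 3 fell, with 4 not called (8 and 4 adjusted over the list alone, camera adjusted p = 0.215), with Acta2 rising from 0.693 ± 0.635 to 218 ± 93.2 FPKM. Cd68 of the macrophage list fell from 6.76 ± 0.191 to 2.19 ± 0.20 FPKM, and Pecam1 of the endothelial list stood at 1.8 ± 0.469 and 0.452 ± 0.188 FPKM. With these, 21 of 26 rose and 2 fell, with 3 not called (21 and 3 adjusted over the list alone) among immediate early genes, with Cyr61 rising from 1.34 ± 0.184 to 725 ± 219.9 FPKM. Immediate early genes had a median log2 change of 2.62 (camera adjusted p = 1.58e-05, adjusted p = 0.844 with an estimated correlation). Of p53 target genes, 17 of 22 rose and 1 fell, with 4 not called (18 and 1 adjusted over the list alone), with Cdkn1a rising from 22.4 ± 12.5 to 409.5 ± 105 FPKM. p53 target genes had a median log2 change of 1.99 (camera adjusted p = 0.000256, adjusted p = 0.844 with an estimated correlation). Of DNA replication genes, 1 of 27 rose and 18 fell, with 8 not called (1 and 19 adjusted over the list alone), with E2f1 falling from 66.2 ± 6.58 to 22.5 ± 3.9 FPKM. Replication genes had a median log2 change of -0.76 (camera adjusted p = 0.000169, adjusted p = 0.844 with an estimated correlation). Of G2 and mitosis genes, 1 of 25 rose and 13 fell, with 11 not called (the same counts adjusted over the list alone), with Ccnb1 falling from 141 ± 10.7 to 56.9 ± 12.7 FPKM. Mitotic genes had a median log2 change of -0.66 (camera adjusted p = 0.00203, adjusted p = 0.844 with an estimated correlation). Of cholesterol synthesis genes, 0 of 20 rose and 15 fell, with 5 not called (0 and 16 adjusted over the list alone). Cholesterol synthesis genes had a median log2 change of -0.88 (camera adjusted p = 0.000169, adjusted p = 0.844 with an estimated correlation). Of Hox genes, 0 of 10 rose and 8 fell, with 2 not called (the same counts adjusted over the list alone). Hox genes had a median log2 change of -2.0 (camera adjusted p = 0.00196, adjusted p = 0.844 with an estimated correlation). Of ribosomal protein genes, 1 of 78 rose and 7 fell, with 70 not called (0 and 1 adjusted over the list alone). Ribosomal protein genes had a median log2 change of -0.37 (camera adjusted p = 0.00203, adjusted p = 0.855 with an estimated correlation). Of proteasome genes, 0 of 38 rose and 10 fell, with 28 not called (0 and 1 adjusted over the list alone). Proteasome genes had a median log2 change of -0.34 (camera adjusted p = 0.0213, adjusted p = 0.844 with an estimated correlation).

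The count of called genes was 3478 and 3845 without mSSC replicates 1 and 2. Gfra1 lost its call without mSSC replicate 1 (adjusted p = 0.0632). Without iSC replicate 2, Rec8 (adjusted p = 0.00498) and Rarb (0.0184) were called. The ribosomal and proteasome list calls were lost without iSC replicate 1 (0.417 and 0.181), and the piRNA call without iSC replicate 2 (0.0736). Quantile normalization shifted the median of all genes by -0.10, gave 42.6% of calls as higher in place of 51.2%, and ended the piRNA (0.115, median -0.63) and ribosomal (0.0549, median -0.21) list calls. The median, mean and test did not share a sign for the uncalled differentiating, spermatid, stress response and glycolysis lists.

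**Figure D4:**
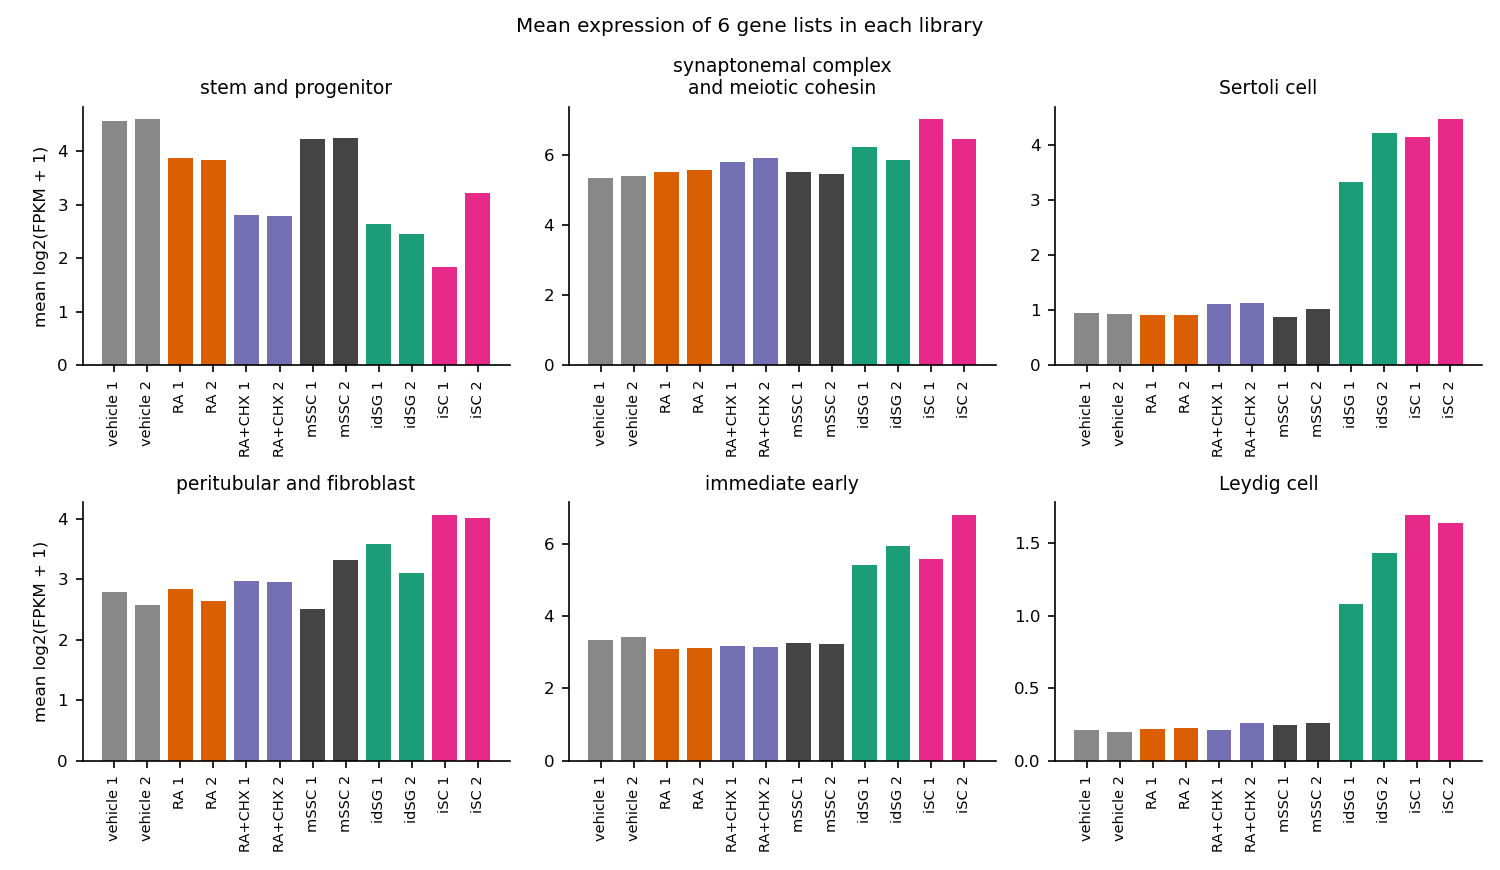
Mean log2(FPKM + 1) of 6 gene lists on the vertical axes, with a bar for each of the 12 libraries on the horizontal axes. The stem and progenitor list stood at 1.84 in iSC replicate 1 and 3.22 in replicate 2, and the Sertoli cell list at 4.14 and 4.46.

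Genes that RA changed on laminin in 24 h were looked up in the induction, where no library is shared. Stra8, Rec8, Rarb and Cyp26a1 rose in both, and Zbtb16, Id4 and Etv5 fell in both. Of 6319 genes called with RA and tested in both experiments, 79.8% had the same sign in idSG against mSSC, compared with 57.4% of the genes not called with RA. Calls overlapped in 993 genes higher in both, where independent lists would share 429, and in 973 lower in both, where independent lists would share 403. Of genes changed at least 2-fold by RA, 138 of 152 had the same sign. Over 11814 genes the changes correlated at r = 0.53 (rho = 0.54), where genes are not independent replicates.

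X-linked genes, which are silenced in pachytene spermatocytes, were higher in iSC than in mSSC, by a median of 0.35 (log2) relative to autosomal genes (camera p = 0.000435, and p = 0.182 with an estimated correlation), but by 0.088 without a filter on low values. Of 531 X-linked genes, 213 rose and 75 fell. Sertoli cell genes were also higher against mSSC (median 3.23 in idSG, 4.14 in iSC), and RNA of other cells was not separated from the X-linked change. In idSG against mSSC the difference was 0.26 (p = 0.000648, and 0.192 with an estimated correlation), with 131 genes higher and 21 lower, and in iSC against idSG it was 0.10 (p = 0.0471, and 0.401). With RA alone, X-linked genes were higher by 0.11 (p = 0.000660, and 0.0318 with an estimated correlation), 186 of 508 rising and 95 falling. With RA and CHX the difference was 0.08 against vehicle and -0.05 against RA, and camera called neither.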

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

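Tests with the Sertoli marker covariate, with repeated lines summed and with the vehicle libraries split between both comparisons were chosen after the results were seen. Fitted on all 12 libraries, limma called 418 genes for RA against vehicle, 6156 for RA and CHX against vehicle, 5712 for RA and CHX against RA, 6513 for idSG against mSSC and 5205 for iSC against idSG. Requiring an absolute log2 change of at least 1 left 171, 1558, 1202, 1925, 558 and 3192 genes over the 6 comparisons. For iSC against idSG the count was 234 on the 2 groups alone, 623 without a filter and 911 with a replicate block. With an estimated correlation camera called 0 lists in each comparison, and 2, 2, 2, 0, 0 and 0 at an unadjusted p under 0.05.

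With the Sertoli score as covariate, limma called 0 genes for idSG against mSSC (910 at an unadjusted p under 0.05), 7 for iSC against idSG (2621) and 0 for iSC against mSSC (772), and camera called 13, 7 and 11 lists. Of the named genes, 15 results changed sign, none of them called with the covariate. In idSG against mSSC the log2 change became -1.23 for Cdkn1a, -0.79 for Cox6b2, -0.35 for Gdf15, -1.90 for Hsd17b3 and -2.33 for Sox9. In iSC against mSSC it became -1.26 for Cdkn1a, -0.081 for Cyp11a1, 1.30 for Fkbp6, -0.33 for Gdf15, 0.54 for Mael, 0.16 for Psmc3ip, 0.54 for Psmc5, 0.089 for Psmd2, -0.33 for Rps4x and -3.15 for Sox9. The same direction of RA genes in idSG fell to 70.8%, and the X-linked difference was 0.64. Without the covariate that difference was 0.35 in the main fit and 0.088 with no filter on low values. The score was -1.12 and -0.98 in mSSC and 1.32 to 2.46 in idSG and iSC, so this fit can hardly tell group from score.

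The share of RA genes kept with CHX was 66.0% with all 12 libraries, 62.7% after quantile normalization, 69.0% by sign alone, and 58.0% and 59.0% with the vehicle libraries split. The share called against the RA change, which includes changes that are only weaker, was 35.4% with all 12 libraries, 41.3% without a filter and 40.5% after quantile normalization. The share with the same direction in idSG was 90.9% with all 12 libraries, 80.9% on the 2 groups alone, 81.4% without a filter and 74.9% after quantile normalization. Over named genes and the settings other than leaving out a replicate, 4573 results were the same, 318 lost a call and 14 gained one.

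Leaving out each replicate, where a lone library is assumed to vary like the other groups, gave 5088 to 6055 genes for RA against vehicle, 9008 to 9773 for RA and CHX against vehicle, 8699 to 9591 for RA and CHX against RA, 961 to 4194 for idSG against mSSC, 8 to 1547 for iSC against idSG and 3478 to 6308 for iSC against mSSC. Counts more than 1.5 times lower are given with each comparison. Lists called were 11 to 13, 9 to 11, 9 to 10, 9 to 13, 5 to 15 and 12 to 15, the 5 without idSG replicate 1. The kept share was 57.5% to 62.4%, the share called against the RA change 39.2% to 43.3%, the same direction 78.2% to 83.4% and the X-linked difference 0.28 to 0.42. Over named genes, 2038 results were the same, 254 lost a call and 8 gained one.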

Other observations

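The 4 gene lists, the single genes named with them and all tests of the 3 patterns below were chosen after the results were seen. The stem list was left out of the estimate for the second pattern, and the rule of its meiotic test was made stricter, after first values had been computed. Endoplasmic reticulum (ER) stress genes, which respond to unfolded protein in the secretory pathway, were higher with RA and CHX than with vehicle, where 23 of 24 rose and 0 fell, with 1 not called (the same counts adjusted over the list alone). ER stress genes had a median log2 change of 0.91 (camera adjusted p = 2.14e-10, adjusted p = 0.149 with an estimated correlation). Hspa5, the main ER chaperone gene, was 221 and 228 FPKM with vehicle and 788 and 769 with RA and CHX, and Herpud1 was 10.4 and 11.6 and then 85.0 and 87.7. Against RA alone, 24 of 24 rose and 0 fell, with 0 not called (the same counts adjusted over the list alone). ER stress genes had a median log2 change of 0.94 (camera adjusted p = 4.33e-11, adjusted p = 0.136 with an estimated correlation). With RA against vehicle, 7 of 24 rose and 8 fell, with 9 not called (7 and 9 adjusted over the list alone, camera adjusted p = 0.536). Heat shock genes were lower as a list with RA and CHX than with vehicle, where 3 of 20 rose and 13 fell, with 4 not called (the same counts adjusted over the list alone), and Hspa8 was 2051 and 1973 FPKM with vehicle and 263 and 240.1 with both. Heat shock genes had a median log2 change of -0.57 (camera adjusted p = 0.0135, adjusted p = 0.336 with an estimated correlation). With RA alone, 0 of 20 rose and 11 fell, with 9 not called (the same counts adjusted over the list alone). Their median log2 change was -0.17 (camera adjusted p = 0.00777, adjusted p = 0.731 with an estimated correlation). With RA and CHX against RA, 6 of 20 rose and 13 fell, with 1 not called (the same counts adjusted over the list alone, camera adjusted p = 0.157). Of imprinted genes with RA and CHX against vehicle, 4 of 18 rose and 13 fell, with 1 not called (the same counts adjusted over the list alone), with Mest at 47.5 and 41.1 FPKM and then 7.34 and 7.23. Imprinted genes had a median log2 change of -0.71 (camera adjusted p = 0.0271, adjusted p = 0.336 with an estimated correlation).

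In idSG against mSSC, NF-kB and chemokine genes were higher, where 9 of 14 rose and 0 fell, with 5 not called (10 and 0 adjusted over the list alone). NF-kB and chemokine genes had a median log2 change of 3.02 (camera adjusted p = 0.00137, adjusted p = 0.517 with an estimated correlation). Cxcl1 was 1.67 and 7.96 FPKM in mSSC and 187 and 802 in idSG. The Sertoli list mean was 3.32 and 4.22 in the same 2 libraries, so the higher replicate was the same for both and the cell type behind the chemokine genes stays open. The heat shock genes Hspa1a and Hspa1b stood at 5.28 and 8.82 FPKM in iSC replicate 1 and at 439.5 and 484 in replicate 2. The fibroblast genes Dcn and Lum stood at 8.22 and 2.58 FPKM in mSSC replicate 1 and at 38.8 and 18.9 in replicate 2.

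Sertoli cell genes were higher in the sorted induced cells than in mSSC, although sorting for GFP should remove unlabelled feeder cells. Over the 16 called members, idSG replicate 2 exceeded replicate 1 by a median log2 ratio of 1.45 (SD 0.58, 93.75% on that side). Their ratio in iSC was 0.35. In idSG it was 0.22 over 2249 other genes called higher, perhaps at another pseudocount, so this contrast is loose. Feeder RNA stays a candidate source. Clu was 292, 743, 1212 and 2111 FPKM in the idSG and iSC libraries, Vim 373, 662, 604 and 971, and Inha 113, 249.9, 561 and 326. An effect of RA on these genes within 24 h is argued against by a median change of 0.013 (SD 0.25, highest 0.60). The same members changed by 4.04 in idSG. In the treatment libraries, 8 of the 27 Sertoli members reached 1 FPKM on average. The Rhox list, also written before the test, covers Rhox5 of the Sertoli list. Whether the induced germ cells express these genes stays open and untested, as no Sertoli library is among the 12.

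Stem cell genes were higher in iSC replicate 2 than in replicate 1, by a median log2 ratio of 1.37, with 24 of 27 members higher. Over 119 other genes lower at day 3, adding a median of 17.7% of mSSC RNA (quartiles 11.3% and 27.3%) would turn replicate 1 into replicate 2, and the share was above 0 for 95.8% of them, so undifferentiated c-KIT-negative cells, which the gate keeps, may be a source. More Sertoli RNA is argued against, since the stem list differed by -0.20 (SD 0.43) between the idSG replicates whose Sertoli genes differed. The 26 meiotic genes called higher in iSC were all below the level this mixture predicts, by a median of -0.42 (SD 0.17), and their ratio of -0.61 lies below the -0.46 that the upper quartile share would give, a bound from an assumed profile, so whether those cells are the whole cause cannot be told apart from slower progress of replicate 2.

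Stem cell genes were lower with RA and CHX than with RA alone, by a median of -1.12 (log2, 28 members). A general fall at this expression level is argued against by 10000 matched random lists (median of medians -0.03, lowest -0.62). These ignore stem gene correlation (camera adjusted p = 0.467 with it estimated) and RNA stability. Scaling is argued against by a median of -0.87 after quantile normalization (shift SD 0.15). An effect of CHX alone stays untested, as no library had it.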
